A study of Rattus norvegicus with 32 samples.

How the data were processed

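Single-nucleus RNA sequencing was done on 32 whole neonatal rat brains, 16 Control and 16 IVH. Per the labels' protocols, 30 µl of lysed blood from a female donor, or of sterile artificial cerebrospinal fluid, was injected into the right ventricle at 0.5 µl per second. The meninges were removed, the brains were frozen, and nuclei were processed with the Chromium GEM-X 3' kit, version 4, and sequenced on a NovaSeq instrument. The authors made the deposited counts with Cell Ranger (version not given in the sources used here), as raw UMI counts per gene and barcode, with no normalization and no selection of nuclei. The genome build, annotation release and intron setting are not given in the sources used here. Gene positions were taken from the GRCr8 annotation by symbol, which held 83.5% of the symbols.

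Nuclei were called in each library from the raw barcodes. A nucleus had at least 10% of the 99th percentile of the UMIs in the top barcodes, whose number was the stated 161933 nuclei divided by the 32 brains. It also had at least 500 UMIs and 300 genes and under 5% mitochondrial UMIs. The UMI thresholds so reached were between 796 and 1941. The nuclei with the highest Scrublet doublet scores (scanpy 1.11.5) were removed, 0.4% per 1000 nuclei called, which took out 1626 of 112715 nuclei (1.44%). The 111089 nuclei kept were 68.6% of the stated number and held between 52.6% and 69.9% of a library's UMIs.

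The counts were scaled to 10000 per nucleus and log-transformed, and 3000 variable genes, 40 principal components and 20 neighbours were used for Leiden clustering at resolution 1.2 with seed 0 (igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0). A cluster took a cell type's name, with the suffix "-like", when its marker list scored at least 1.4 and led the next list by 0.5, with at least 3 markers detected in at least 10% of its nuclei. It kept its number if another list had more markers than its own among its 10 leading genes by fold, or if its library's median UMIs were over 3 times its own and none of its own markers were among these. By the former rule cluster 17 (best list cycling progenitor, score 4.49) and cluster 49 (inhibitory neuron, 1.96) stayed numbered. In all, 73.2% of nuclei had a named class. Clusters of 1 name were joined, without correction between libraries. Median genes per nucleus ranged from 1201 to 2503 over the libraries. Between libraries of 1 group the chi-square per degree of freedom of the counts, where counting error alone gives about 1, was 2.66 to 32.8 over 120 Control pairs and 2.86 to 25.8 over 120 IVH pairs. Taken over all genes, the spread between libraries thus exceeded counting error. This was not measured for single genes of low count or for small classes, where counting error may weigh more.

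The brain was the replicate. Counts were summed per library over each class with at least 20 nuclei in at least 12 libraries per group, over all nuclei, and over all barcodes of at most 100 UMIs. 15 classes, 9 of them named, met this minimum. IVH was compared with Control by the edgeR quasi-likelihood test (edgeR 4.0.16, filterByExpr, TMM) in R 4.3.3, with the Benjamini-Hochberg adjustment over the genes of each sum and a threshold of 0.05. Shares of nuclei, measures of quality and differences of a list's effect between classes were compared by two-sided permutation tests with 100000 resamples (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). Values in CPM are means over the libraries of each library's counts scaled to its total after TMM. Age and sex were no covariates, since the labels give neither per library. The test code was tested on simulated data made from these counts, with 200 changed genes in each sum and every gene drawn independently. Of genes changed 1.5-fold, 90.0% were recovered over all nuclei, 84.8% in barcodes of at most 100 UMIs and 54.4% in microglia or macrophage-like nuclei. With few changed genes the adjustment is stricter, so these shares do not give the power of the comparisons below.

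25 gene lists written from general knowledge were tested by camera (limma 3.58.1) with a preset correlation of 0.01, where at least 5 members were measured, with camera at an estimated correlation and fry beside it. They covered activated phagocyte, homeostatic microglia, complement, interferon response, NF-kB cytokine and chemokine, neutrophil and other blood leukocyte, reactive astrocyte, erythroid and reticulocyte, heme, iron and haptoglobin, and NRF2 genes. They also covered hypoxia and glycolysis, integrated stress, heat shock, p53 and cell death, immediate early, glucocorticoid, cell cycle, neuronal differentiation, synapse, and oligodendrocyte and myelin genes. The remaining lists held blood-brain barrier, endothelial activation, extracellular matrix, choroid transport and motile cilium genes.

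Genes were named by a rule. Per class with a call, up to 6 genes in each direction with the largest log2 fold change and at least 10 CPM in the higher group were named, and over all nuclei up to 15. Members past 0.05 of a list that passed were named too, and in a class without a call the 3 genes with the smallest p. Hmox1, Gfap, Ttr, Aif1, Cdkn1a, Vegfa and the haemoglobin genes were named whatever their result. Genes without a symbol and sex-linked marker genes were counted and not named.

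The alternatives were DESeq2 1.42.0, no low-count filter, surrogate variables from sva 3.50.0, a covariate for depth, the 30 libraries of 1 name series, nuclei of at least 1000 UMIs, doublets kept, at least 50 nuclei per library, barcodes of at most 50 UMIs, and a centred log-ratio with 0.5 added. Added after the data were seen were all barcodes of at least 500 UMIs, 137813 in number, a fit without cerebellar-type clusters, at least 10 nuclei per library for 3 classes, lists over all nuclei and in barcodes of at most 100 UMIs, and fits that left out each library. Also added then were the block of deposit order (replicates 1 to 8 and 9 to 16 of each group) as a term or as the bounds of a permutation, and the share of the cerebellar-type clusters as a covariate in the list tests. Python 3.11.15 and matplotlib 3.10.9 were used. Comparisons between days and between sexes were left out because the labels do not give them per library. Some list and marker genes, among them Cldn5, Foxj1, Cd36 and Fcrls, were not analysed here.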

Results

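RNA was counted in single nuclei from 32 whole brains of neonatal Sprague Dawley rats. Intraventricular haemorrhage (IVH), a bleed into the brain's ventricles that affects preterm infants, was modelled by injecting 30 µl of lysed blood into the right ventricle, and Control animals received 30 µl of artificial cerebrospinal fluid. Per the design text, the injection took place on postnatal day 2 or 5 and the brain was collected 24 h later, with 8 brains per treatment and day and 4 of each sex. The labels give each library's treatment, 16 Control and 16 IVH, but not its day or sex, so days and sexes were pooled and were not compared.

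UMIs (unique molecular identifiers), which count single RNA molecules, gave the depth of each library. Each library held between 17055956 and 36940407 UMIs. In all, 111089 nuclei were kept, 54101 from Control and 56988 from IVH brains, with 2780 to 4826 nuclei per library. The median UMIs per nucleus ranged from 2019 to 5780 over the libraries. Control and IVH libraries did not differ detectably in depth or quality. Nuclei per library averaged 3381 ± 515 (SD, n = 16) in Control and 3562 ± 548 (n = 16) in IVH, with 12 of 16 IVH libraries above the Control median (two-sided permutation test, p = 0.348, adjusted p = 0.696). Median UMIs per nucleus averaged 3345 ± 873 and 2968 ± 498, with 4 of 16 IVH libraries above the Control median (p = 0.147, adjusted p = 0.589). The mitochondrial share of UMIs was 0.279% ± 0.0886 and 0.286% ± 0.0605 (7 of 16 above, p = 0.811, adjusted p = 0.894). The share of UMIs in barcodes of at most 100 UMIs was 27.9% ± 4.50 and 28.1% ± 5.25 (8 of 16 above, p = 0.894, adjusted p = 0.894). The library names form 2 series, of which the smaller holds 2 Control libraries only, so values within 1 name series come from the other 30 libraries. Within those 30, each of the 4 measures had an adjusted p of 0.968. The libraries also parted by order of deposit into a block of replicates 1 to 8 and one of replicates 9 to 16, each with 8 libraries per group. Between the blocks the median chi-square per degree of freedom of the counts of 2 libraries was 16.4 in Control and 13.5 in IVH, and within them it was 5.48 to 9.12 and 5.48 to 9.29. The 30 libraries of 1 name series span both blocks. No label says what sets the blocks apart, and a fit with the block as a term was added after the data were seen.

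The nuclei formed 51 clusters, of which 32 were named from a marker list and were joined into 15 named classes, and 19 stayed numbered. Excitatory neuron-like nuclei made up 31.0% of nuclei, inhibitory neuron-like 12.6%, astrocyte or radial glia-like 7.60%, striatal projection neuron-like 6.69%, cycling progenitor-like 4.45%, oligodendrocyte precursor-like 4.37% and microglia or macrophage-like 1.13%. The cycling progenitor-like class joined cluster 22 (3351 nuclei, second list astrocyte or radial glia) and cluster 26 (1594 nuclei, second list oligodendrocyte precursor). Whether IVH shifted their mix was not tested. Purkinje neuron-like nuclei and clusters 5, 17, 36 and 40 (led by genes such as Pax3, Ebf3, Pax2 and Fat2) were almost absent from 7 Control and 4 IVH libraries, all of them in the block of replicates 9 to 16. The endothelial-like class also carried haemoglobin RNA, with 33639 ± 26059 CPM of Hbb (CPM being counts scaled to a common library size) in Control.

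The first comparison asked whether IVH altered the RNA outside nuclei, that is, in barcodes of at most 100 UMIs, which hold free RNA and debris and where RNA of the injected blood would appear. Genes of phagocytes that clear debris were higher after IVH. Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1 (ENSRNOG00000014117, chromosome 19, 13452365 to 13479823 in the GRCr8 annotation), rose from 3.04 ± 1.00 CPM (SD, n = 16) to 9.42 ± 3.84 CPM (n = 16). Its log2 fold change was 1.66 ± 0.19 (SE; edgeR adjusted p = 3.26e-06), and all 16 IVH libraries lay above the highest Control library. Spp1 (ENSRNOG00000043451), which encodes the secreted phosphoprotein osteopontin, rose from 22.6 ± 8.27 to 94.2 ± 59.2 CPM, a log2 fold change of 2.07 ± 0.28 (edgeR adjusted p = 4.06e-05), with 16 of 16 IVH libraries above the Control median. Msr1, a macrophage scavenger receptor (ENSRNOG00000012779), rose from 1.61 ± 0.61 to 5.40 ± 2.27 CPM, a log2 fold change of 1.72 ± 0.21 (edgeR adjusted p = 6.21e-06, 16 of 16).

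Lyz2, encoding lysozyme, had a log2 fold change of 1.28 ± 0.23 (edgeR adjusted p = 0.00328, 15 of 16 IVH libraries above the Control median). Lgals3, encoding galectin-3, rose by 1.24 ± 0.18 (adjusted p = 0.000149, 15 of 16), and Gpnmb, a glycoprotein of phagocyte lysosomes, by 1.23 ± 0.18 (adjusted p = 0.000149, 16 of 16). The Fc receptor gene Fcgr3a rose by 1.02 ± 0.18, the lysosomal gene Cd68 by 0.76 ± 0.13 and the cathepsin gene Ctsz by 0.67 ± 0.11, in at least 15 of 16 libraries and with adjusted p of at most 0.00353. Of the complement genes, C1s rose by 0.60 ± 0.11 (adjusted p = 0.00865, 15 of 16), Cfb by 0.48 ± 0.11 (adjusted p = 0.0472, 15 of 16) and C1r by 0.41 ± 0.09 (adjusted p = 0.0483, 14 of 16). Cd74 and RT1-Da, both of antigen presentation on MHC class II, rose by 1.39 ± 0.28 and 1.87 ± 0.37 (adjusted p = 0.0130 each, 15 and 14 of 16) and were picked out only after their values were seen. Genes typical of resting microglia did not move with these: P2ry12 had a log2 fold change of -0.35 ± 0.18 and Csf1r of 0.08 ± 0.14 (adjusted p = 1.00 each). Haemoglobin RNA was abundant in both groups, with Hbb at 1608 ± 563 CPM in Control and 1894 ± 928 CPM in IVH (log2 fold change 0.24 ± 0.22, adjusted p = 1.00, 10 of 16) and Hba-a1 at 937 ± 379 and 1056 ± 409 CPM (0.17 ± 0.21, adjusted p = 1.00, 13 of 16).

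Of 13494 genes tested in this RNA, 23 were higher and 0 lower after IVH (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 471, and DESeq2 called 52 higher and 3 lower, among them all 23. Chance alone would put a share of 0.05 of the genes tested under that level, so such unadjusted counts, here and below, are no sign of change by themselves. With surrogate variables 96 were higher and 9 lower, all 23 among them. Within the 30 libraries of 1 name series 15 of the 23 passed and no other gene did, and with at most 50 UMIs per barcode 13 of them did. With the block of deposit order as a term 29 genes were higher and 0 lower (edgeR, 781 at an unadjusted p under 0.05), the 23 included. When each library was left out in turn, 14 of the 23 passed every time, Hmox1, Spp1, Msr1, Gpnmb, Lgals3 and Lyz2 among them, while Cfb and C1r passed in 8 and 7 of 32 fits. The count was 14 without Control replicate 7 and 15 without IVH replicate 16.

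**Figure D1:**
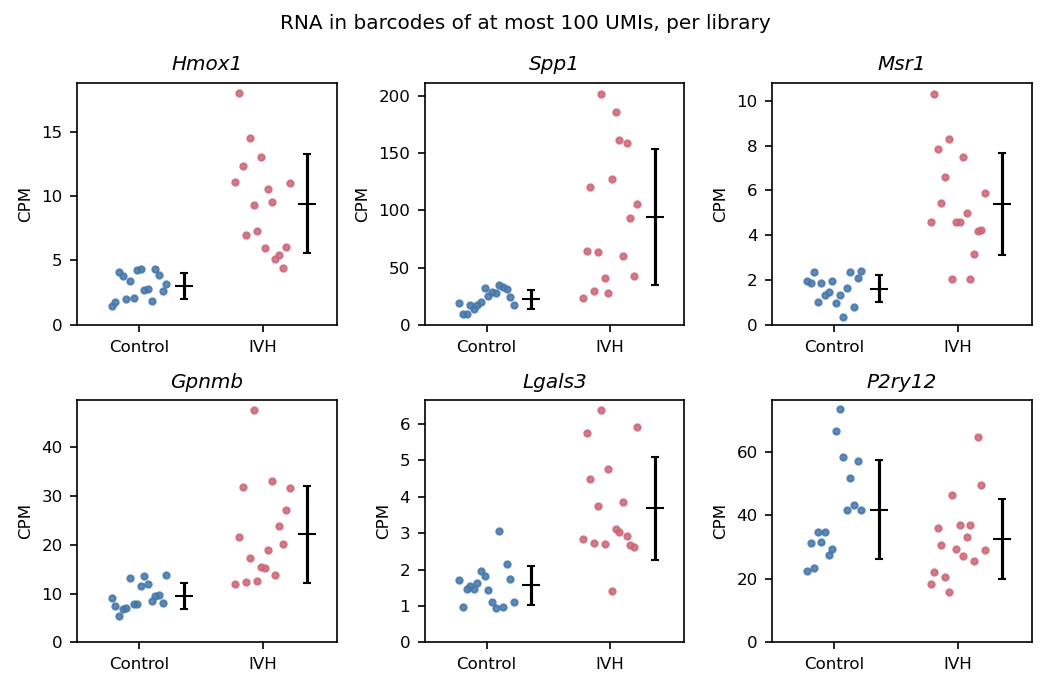
CPM of 6 genes in barcodes of at most 100 UMIs, 1 point per library, 16 Control and 16 IVH; the bars show mean ± SD. Hmox1 in the IVH libraries lies above every Control library, while P2ry12, a gene of resting microglia, overlaps (Control 22.5 to 73.4 CPM, IVH 15.9 to 64.6 CPM).

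The second comparison asked which genes differed when counts were summed over all nuclei of a brain. 6 genes were higher after IVH, of which the 5 described here include genes of microglia and other leukocytes. Apobec1 (ENSRNOG00000015411), an mRNA-editing cytidine deaminase, rose from 2.74 ± 1.34 to 5.97 ± 1.49 CPM, a log2 fold change of 1.12 ± 0.18 (edgeR adjusted p = 0.00331, 16 of 16 IVH libraries above the Control median). Spp1 rose from 0.743 ± 0.429 to 2.48 ± 1.67 CPM, a log2 fold change of 1.72 ± 0.32 (adjusted p = 0.0256, 15 of 16). Ly86, which encodes a partner protein of a Toll-like receptor relative, rose by 0.99 ± 0.19 (adjusted p = 0.0354, 15 of 16). The leukocyte integrin gene Itgal rose by 1.08 ± 0.22 (adjusted p = 0.0376, 15 of 16). Cp, encoding the iron-oxidising protein ceruloplasmin, rose by 0.28 ± 0.05 (adjusted p = 0.0373, 14 of 16). Apobec1, Ly86 and Itgal lay below the level of the naming rule and were named only after their values were seen.

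Of 13938 genes tested, 6 were higher and 0 lower (edgeR), 623 had an unadjusted p under 0.05, and DESeq2 called 18 higher and 1 lower, all 6 among them, and surrogate variables gave 22 higher and 6 lower, again with all 6. Apobec1 passed whichever library was left out, whereas Spp1 passed in 26, Ly86 in 16, Cp in 13 and Itgal in 10 of 32 such fits. Leaving out Control replicate 7 or 9 or IVH replicate 2, 3, 10 or 11 left 2 genes each, Control replicate 6, 8, 10, 13 or 15 or IVH replicate 4 or 5 left 3 each, and Control replicate 1 or IVH replicate 6 gave 10 each and IVH replicate 9 gave 11. Within the 30 libraries of 1 name series 10 genes passed, the 6 included, and with the block of deposit order as a term 9 passed, again with the 6 included. Of the 12 genes called in the barcodes of at most 100 UMIs that were also tested here, all 12 were higher in IVH, with a median log2 fold change of 0.49, and 2 passed. Background RNA was not removed from the nuclei, so these 2 sums of counts are not independent.

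**Figure D2:**
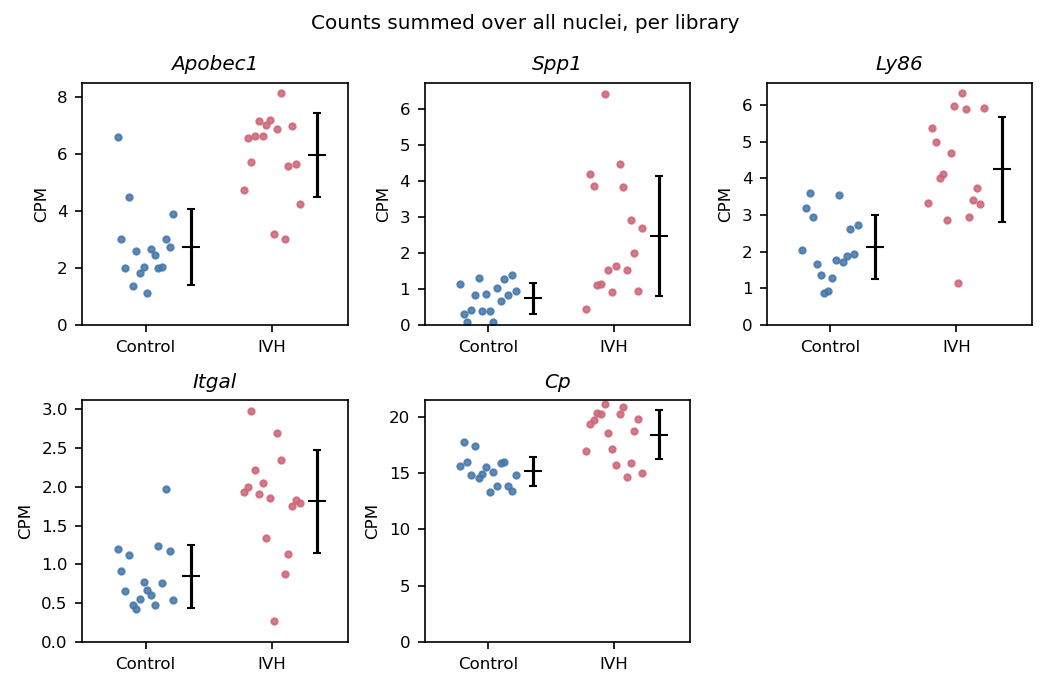
CPM of 5 of the genes called over all nuclei, 1 point per library, 16 Control and 16 IVH; the bars show mean ± SD. Of the 16 IVH libraries, 11 lie above every Control library for Spp1 and 8 for Apobec1.

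The third comparison asked whether IVH altered the share of each cell class among the nuclei. Microglia or macrophage-like nuclei, the immune cells of the brain, made up 0.967% ± 0.268 (SD, n = 16) of nuclei in Control and 1.29% ± 0.336 (n = 16) in IVH, with 12 of 16 IVH libraries above the Control median. That difference of 0.321 percentage points did not pass the adjustment over 34 classes (two-sided permutation test, p = 0.00590, adjusted p = 0.201). Cluster 40, led by Fat2 and Neurod1 and 1 of the clusters missing from some libraries, made up 1.42% ± 1.36 and 2.65% ± 1.93 (p = 0.0449, adjusted p = 0.764, 12 of 16). None of the 34 classes passed, and 2 had an unadjusted p under 0.05. The edgeR test of nuclei counts also called 0 classes, with an adjusted p of 0.309 for microglia. Within the 30 libraries of 1 name series the microglial difference was 0.333 points (adjusted p = 0.254), and as a centred log-ratio it was 0.261 (p = 0.255, adjusted p = 0.578). Over all barcodes of at least 500 UMIs it was 0.0970 points (p = 0.588, adjusted p = 0.949). Shuffled within the blocks of deposit order it had p = 0.00539 and an adjusted p of 0.183, with means of 0.810% and 1.31% in replicates 1 to 8 and 1.12% and 1.27% in replicates 9 to 16.

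**Figure D3:**
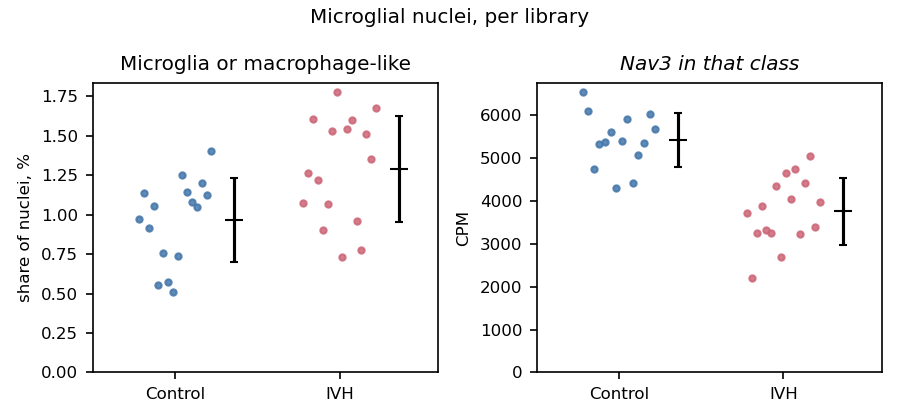
Share of microglia or macrophage-like nuclei in percent (left) and CPM of Nav3 in those nuclei (right), 1 point per library; the bars show mean ± SD. The share had means of 0.967% and 1.29%, and Nav3 ranged from 4302 to 6541 CPM in Control and from 2203 to 5047 CPM in IVH.

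The fourth comparison asked which genes differed within a cell class. In microglia or macrophage-like nuclei, Nav3 (ENSRNOG00000052157), which encodes a microtubule-associated protein of the neuron navigator family, fell from 5415 ± 636 CPM (SD, n = 14) to 3758 ± 778 CPM (n = 16). Its log2 fold change was -0.53 ± 0.10 (SE; edgeR adjusted p = 0.0264), and 16 of 16 IVH libraries lay below the Control median. In cluster 18, which took no name and was led by Rnf220, Ntng1 and Lef1, 1 gene was lower and is not described here. With surrogate variables 1 other gene was higher there and 0 lower (edgeR, 271 at an unadjusted p under 0.05), so that call was lost. Within the 30 libraries of 1 name series neither class had a call, and with the block of deposit order as a term each had 1, Nav3 again in microglia (adjusted p = 0.0199). Nav3 passed in 20 of 30 fits that left out 1 library, being lost without Control replicate 1, 2, 6 or 11 or IVH replicate 3, 5, 8, 12, 15 or 16, with an adjusted p of at most 0.0663.

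In the other 13 classes edgeR called 0 genes, with 41 to 337 genes per class at an unadjusted p under 0.05, and DESeq2 also called 0, with 249 to 449. By edgeR excitatory neuron-like nuclei had 245 of 11451 genes, below the share of 0.05 that chance alone gives, and 511 with the block of deposit order as a term. Fibroblast-like (132 of 2523) and oligodendrocyte precursor-like nuclei (264 of 5133) lay slightly above that share. The 0 calls therefore do not show that these classes lacked a response. The genes with the smallest p in these classes are given as not passing, each with its log2 fold change. In astrocyte or radial glia-like nuclei they were Pdgfd (-0.40) and Cpne8 (0.82), a further gene being left out here. In cycling progenitor-like nuclei they were Gfap (1.08), Tspan5 (-0.26) and Vegfa (0.40), and in oligodendrocyte precursor-like nuclei Hbb (3.38), Hba-a1 (2.82) and Man1a2 (0.34). In neurons they were Gga1 (-0.27), Usf3 (-0.19) and Creb5 (0.69) for the excitatory class, Gtf2h5 (-0.42), Fcho1 (-0.28) and Anxa5 (-0.44) for the inhibitory class, and Tomm20 (0.46), Letm1 (-0.41) and Sel1l3 (0.44) for the striatal class. In ependymal-like nuclei they were Zc2hc1a (0.52), Dnajc6 (-0.55) and Nckap5 (-0.35), and in fibroblast-like nuclei Slc2a12 (0.67), Zeb1 (-0.29) and Add3 (0.32). In the numbered clusters they were Eya2 (0.67), Atxn7l2 (0.37) and Apoo (-0.16) for cluster 7, Maf (-0.59), Nr3c2 (-0.76) and Pdxdc1 (0.47) for cluster 8, Cacna2d1 (0.42), Pikfyve (-0.52) and Nrbp2 (-0.50) for cluster 10, Smc5 (-0.37), Actb (0.58) and Slmap (0.40) for cluster 33, and Sema5a (0.64), Erc1 (0.36) and Csmd2 (0.35) for cluster 37. With the block of deposit order as a term 3 genes of these 13 classes passed (edgeR): Maf in cluster 8 (-0.59, adjusted p = 0.0298, 13 of 15 IVH libraries below the Control median), Creb5 in excitatory neuron-like nuclei (0.69, adjusted p = 0.0243, 13 of 16 above) and Hbb in oligodendrocyte precursor-like nuclei (3.30, adjusted p = 0.0199, 9 of 16 above). The last rested on IVH replicate 13, without which Hbb had 0.20 in the fit without the block. Endothelial-like, oligodendrocyte-like and choroid plexus epithelial-like nuclei were too few for the planned minimum of 20 nuclei per library and were tested at 10, a choice made after the data were seen. There edgeR called 0 genes, with 48 to 100 at an unadjusted p under 0.05, and DESeq2 called 0, with 239 to 270. The smallest p belonged to Cpeb2 (0.61), Mt-co3 (-0.84) and Clu (-0.56) in choroid plexus, Mettl6 (0.40), Gne (-0.67) and Itga6 (-0.38) in endothelial, and Map3k2 (-0.51), Osbpl8 (-0.51) and Ylpm1 (-0.48) in oligodendrocyte-like nuclei.

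Several genes were fixed for naming whatever their result. Gfap, the intermediate filament gene of astrocytes, had a log2 fold change of 0.46 ± 0.13 over all nuclei (edgeR adjusted p = 0.428, 12 of 16 IVH libraries above the Control median) and 0.30 ± 0.14 in astrocyte or radial glia-like nuclei (adjusted p = 0.999, 10 of 16). In cycling progenitor-like nuclei Gfap had 42.6 ± 22.5 CPM in Control and 90.7 ± 53.3 CPM in IVH, which did not pass (a log2 fold change of 1.08 ± 0.24, adjusted p = 0.320, 14 of 16). The angiogenic factor gene Vegfa had 0.40 ± 0.10 in those nuclei (adjusted p = 0.332, 16 of 16) and 0.09 ± 0.06 over all nuclei (adjusted p = 1.00, 12 of 16). Ttr, the transthyretin gene of the choroid plexus, had -0.42 ± 0.17 in choroid plexus epithelial-like nuclei (adjusted p = 0.814, 3 of 16 above) and -0.12 ± 0.24 over all nuclei (adjusted p = 1.00, 6 of 16 above). The cell cycle inhibitor gene Cdkn1a had -0.0097 ± 0.14 over all nuclei (adjusted p = 1.00, 7 of 16 above), and the microglial gene Aif1 had 0.35 ± 0.18 in barcodes of at most 100 UMIs (adjusted p = 1.00, 11 of 16). In fits without the count filter Aif1 had -0.03 ± 0.24 over all nuclei, with 99 UMIs in Control and 95 in IVH (edgeR adjusted p = 0.997). In microglia or macrophage-like nuclei it had -0.44 ± 0.32 in such a fit (adjusted p = 0.800). Over all nuclei Hmox1 did not pass the count filter, with 103 UMIs in Control and 206 in IVH, and in the fit without that filter its log2 fold change was 1.02 ± 0.28 (adjusted p = 0.346). In such fits it had 0.61 ± 0.39 in microglia or macrophage-like nuclei (36 and 86 UMIs, edgeR adjusted p = 0.793). It had 2.35 ± 0.64 in cycling progenitor-like nuclei (1 and 14 UMIs, adjusted p = 0.658) and -0.17 ± 0.45 in endothelial-like nuclei (33 and 28 UMIs). These few UMIs do not show which class carried its rise. Over all nuclei Hbb had a log2 fold change of 0.12 ± 0.45 and Hba-a1 of 0.0061 ± 0.45 (adjusted p = 1.00 each, 10 and 11 of 16), which without Control replicate 7 were 0.53 ± 0.42 and 0.38 ± 0.42. In oligodendrocyte precursor-like nuclei the Hbb value of 3.38 ± 0.72 (adjusted p = 0.0931, 9 of 16) rested on IVH replicate 13, at 5701 CPM, and without it was 0.20 ± 0.23. The Hba-a1 value of 2.82 ± 0.65 there (adjusted p = 0.169, 10 of 16) rested on the same library, at 2609 CPM against 61.2 in the next, and without it was 0.30 ± 0.22. Hba-a3 had 0.35 ± 0.46 over all nuclei (adjusted p = 1.00, 11 of 16), and Hbe1 and Hbg1, with 4 Control UMIs each over all nuclei, did not pass the count filter. In the fit without it Hbe1 had -0.95 ± 0.58 (adjusted p = 0.936) and Hbg1 0.44 ± 0.60 (adjusted p = 0.985).

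The fifth comparison asked whether lists of genes fixed in advance moved together within a cell class. In microglia or macrophage-like nuclei camera with a preset correlation called genes of the cell cycle upwards and genes of resting microglia downwards, and neither call held with an estimated correlation (adjusted p = 0.795 and 0.735). The 7 cell cycle genes measured there had a median log2 fold change of 0.45 (camera adjusted p = 0.00234), with Ect2 at 0.77 ± 0.25, Cenpf at 0.68 ± 0.28 and Mki67 at 0.45 ± 0.25, each of them higher than the Control median in at least 12 of 16 IVH libraries. The 10 homeostatic microglia genes had a median of -0.23 (camera adjusted p = 0.00234), with the receptor gene Gpr34 at -0.51 ± 0.18 and the TGF-beta receptor gene Tgfbr1 at -0.32 ± 0.12. In cycling progenitor-like nuclei the 8 hypoxia and glycolysis genes had a median of 0.17 (camera adjusted p = 0.00647, and 0.117 with an estimated correlation), with Vegfa at 0.40 ± 0.10, P4ha1 at 0.26 ± 0.11 and Pfkp at 0.26 ± 0.12. Of the members of the lists tested in classes, 0 passed over all genes tested (edgeR) and 10 passed adjusted over the list alone, among them Ect2 and Vegfa. These were 3 of 115 pairs of 20 lists and 15 classes, and fry, a rotation test of whether a list moves 1 way, called 0 pairs. The next pair, motile cilium genes in cluster 10, had a camera adjusted p of 0.114.

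The same lists were also tested over all nuclei and in barcodes of at most 100 UMIs, a choice made after the data were seen. In the low-UMI barcodes, activated phagocyte genes rose as a list (18 members, median 0.13, camera adjusted p = 3.26e-17), with 5 members past 0.05 over all genes tested and 6 adjusted over the list alone. Complement genes were higher too (11 members, median 0.22, adjusted p = 3.37e-12), with 3 members over all genes and 5 adjusted over the list alone. Cell cycle genes (24 members, median 0.23, adjusted p = 6.01e-20) and reactive astrocyte genes (15 members, median 0.24, adjusted p = 3.89e-08) rose with 0 members past 0.05 over all genes (edgeR) and with 8 and 3 adjusted over the list alone. These 4 lists held with an estimated correlation, with adjusted p of 0.00102, 0.00204, 0.0110 and 0.0110. Cluster 17, whose own best list was cycling progenitor markers but which took no name and is 1 of the clusters missing from some libraries, made up 1.10% ± 1.07 of nuclei in Control and 1.65% ± 1.15 in IVH (p = 0.170, adjusted p = 0.790, 11 of 16). With the share of the cerebellar-type clusters as a covariate, a choice made after the data were seen, cell cycle genes in the low-UMI barcodes kept an adjusted p of 0.00473 with an estimated correlation, and reactive astrocyte genes did not hold (adjusted p = 0.0525). 10 further lists passed with the preset correlation only, with adjusted p of 0.142 to 0.373 under an estimated correlation. Higher among them were heat shock and protein folding, interferon response, integrated stress response, immediate early genes, neuronal differentiation and axon growth, and oligodendrocyte differentiation and myelin, and lower were blood-brain barrier, homeostatic microglia genes and motile cilium. The heme, iron and haptoglobin list passed upwards although its median was -0.0024 and its mean 0.13, Hmox1 being its only member past 0.05.

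Over all nuclei 6 lists were higher with the preset correlation. Complement genes (12 members, median 0.34, camera adjusted p = 2.05e-08) held with an estimated correlation (adjusted p = 0.00214), with 1 member past 0.05 over all genes tested and 1 adjusted over the list alone. Cell cycle genes (24 members, median 0.21, adjusted p = 1.88e-14), activated phagocyte genes (median 0.06, adjusted p = 3.09e-05), interferon response genes (median 0.17, adjusted p = 0.000644), oligodendrocyte differentiation and myelin genes (median 0.20, adjusted p = 0.00141) and homeostatic microglia genes (median 0.08, adjusted p = 0.00448) did not hold, with adjusted p of 0.144, 0.0639, 0.128, 0.346 and 0.255 under an estimated correlation. Without the cerebellar-type clusters, cluster 17 among them, the cell cycle list had a camera adjusted p of 2.46e-15 and an adjusted p of 0.0539 with an estimated correlation. No class and neither of these sums called the NRF2 oxidative stress response, NF-kB cytokines and chemokines, p53 and cell death, erythroid and reticulocyte RNA, endothelial activation and angiogenesis, choroid ion and water transport, extracellular matrix and fibrosis, glucocorticoid response or glutamate and GABA synapse lists. The neutrophil and other blood leukocyte list had fewer than the 5 measured members needed in every sum of counts. Its 4 members in barcodes of at most 100 UMIs had a median log2 fold change of -0.06.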

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

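The tests of cerebellar tissue, of microglial RNA of every kind and of blood leukocytes, the fits that left out 1 library, and the fits and splits with the block of deposit order were chosen only after the results were seen.

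In 7 of 11 comparisons between cell classes, a list's IVH effect differed by a two-sided permutation test of the difference itself. The mean log2 effect on hypoxia and glycolysis genes was higher in cycling progenitor-like nuclei than in cluster 18 by 0.28 (5 shared genes, adjusted p = 0.00341). On 8 shared genes it was higher than in cluster 7 by 0.16 (adjusted p = 0.0233), than in excitatory neuron-like nuclei by 0.133 (adjusted p = 0.0233) and than in inhibitory neuron-like nuclei by 0.126 (adjusted p = 0.0479). The progenitors' own effect was 0.238 on those 5 genes and 0.153 on the 8, so these gaps cannot be ranked against each other. The effect on cell cycle genes was 0.49 higher in microglia or macrophage-like than in cycling progenitor-like nuclei (adjusted p = 0.0479). The latter class took its name from such genes, with Top2a and Cenpf among its leading genes, which limits its own effect (0.0115). This difference therefore adds little to the call in microglia. The homeostatic microglia genes also counted in neurons, 5 per comparison and not separated there from background RNA, differed in microglia by -0.26 from excitatory neuron-like nuclei and by -0.32 from inhibitory neuron-like nuclei (adjusted p = 0.0233 each). All 7 passed within the 30 libraries of 1 name series, with adjusted p of at most 0.0464. The other comparisons, of cycling progenitor-like nuclei with astrocyte or radial glia-like (0.12), oligodendrocyte precursor-like (0.14) and striatal (0.10) nuclei and of microglia with cluster 7 (-0.19), did not pass.

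These lists were picked because camera had called them in 1 of the classes compared, so the differences are not independent of those calls. For the number of pairs of list and class called, 3, chance could not be excluded: 42 of 70 splits of the libraries, the real one included, gave as many, and the highest other split gave 25. The cause of a split with several times the real count was not tested. With the block of deposit order as a term 24 of 60 splits within the blocks still gave 3 pairs or more (highest other 11), and the unlabelled days and sexes were not tested. A proliferating, less homeostatic microglia after IVH may lie behind the cell cycle and homeostatic lists, and a hypoxic response behind Vegfa in progenitors, but none of the 3 calls held with an estimated correlation, so these stay hypotheses. A shift in the mix of the clusters joined as cycling progenitor-like was also not tested.

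The genes higher in barcodes of at most 100 UMIs, led by Hmox1, Spp1 and Msr1, were 23. Of 100 splits that ignored the block of deposit order 1, the real one, gave as many, and the highest other split gave 1. By these splits chance can be excluded, but splits within the blocks, described further below, exclude it only weakly. The share of the cerebellar-type clusters was not used as a covariate for these genes. A different share of UMIs in these barcodes was not seen, with 27.9% in Control and 28.1% in IVH (two-sided permutation test, p = 0.894). All 23 still passed with that share as a covariate, with a median log2 fold change of 1.02 after 1.01. A covariate so alike in both groups could hardly have changed them, so that fit adds no support. A rise of all microglial RNA alike is argued against by 14 homeostatic microglia genes. Their median was -0.0684 ± 0.0692 (SE), where the explanation needed a rise and the genes called had a median of 1.01. They cannot speak against more microglial RNA in which they themselves are lower. Camera with the preset correlation had called them downwards in microglia or macrophage-like nuclei, a call that did not hold with an estimated correlation. Leukocyte RNA from the injected blood stays open, because only 4 leukocyte genes were measured, with a median of -0.0590 ± 0.126 (SE), of which S100a9 lay near the floor and Vcan is also a gene of oligodendrocyte precursors. No biological explanation was tested, and day and sex, which the design text balances between the treatments, were not compared.

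For the 6 genes higher over all nuclei the splits leave chance undecided. Among the 40 splits drawn first 2, the real one included, gave as many, which is not under 0.05. The number was raised to 100 after this was seen. The 2 of 100 that then gave as many (highest other 6) therefore cannot exclude chance. With the block of deposit order as a term 1 of 100 splits within the blocks gave as many as the real 9 genes. That was the real one, the highest other gave 2, and this fit too was chosen after the results were seen. Without the cerebellar-type clusters 6 of the 6 genes passed, so the nuclei of those clusters did not carry the calls. Microglia and other cells of cerebellar tissue stayed in that sum. Cerebellar tissue in more IVH than Control libraries therefore stays open. The parts of a larger share of microglial nuclei and of a change within them cannot be told apart. With that share as a covariate the median log2 fold change was 0.65 after 1.04 and 0 of 6 genes passed. The share's own log2 rise was 0.411 in the edgeR test of nuclei counts. As an estimate that is above the change of Cp and below those of Apobec1, Itgal, Ly86 and Spp1. The spread of the share's rise was not set against theirs, so this does not decide whether the share alone falls short. Background RNA counted with the nuclei was not removed, and its part was not tested. Apobec1 (1.12 ± 0.18, then 0.87 ± 0.17, edgeR adjusted p = 0.186), Itgal (1.08 ± 0.22, then 0.73 ± 0.22, adjusted p = 0.691) and Ly86 (0.99 ± 0.19, then 0.56 ± 0.16, adjusted p = 0.647) ended with smaller folds, whereas Spp1 (1.72 ± 0.32, then 1.64 ± 0.36, adjusted p = 0.215) and Cp (0.277 ± 0.0547, then 0.262 ± 0.0626, adjusted p = 0.377) kept about their folds with a wider spread.

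In barcodes of at most 100 UMIs with the block of deposit order as a term, the real split gave 29 genes. Of 100 splits within the blocks 3, the real one included, gave as many. That is under 0.05, but the highest other gave 995, so with this term chance is excluded only weakly. The cause of that large count was not tested. For the 2 genes called within classes chance could not be excluded, as 14 of 70 splits gave as many and the highest other split gave 15, again several times the real count. With the block of deposit order as a term 7 of 60 splits within the blocks gave the real 5 or more, and the highest other gave 48. Splits of microglia or macrophage-like nuclei and of cluster 18 alone exclude nothing, because these classes were picked for their call. There 3 of 70 splits (3 of the 40 drawn first, highest other 4) and 4 of 70 (highest other 2) gave 1 gene or more, and 1 and 3 of 60 with the block (highest other 0 and 1). For the 6 lists over all nuclei chance could not be excluded, with 19 of 100 splits and 12 lists in the highest other, nor with the block (7 lists, 13 of 100 splits, highest other 13). For the 14 lists in barcodes of at most 100 UMIs, 1 of 100 splits, the real one, gave as many and the highest other gave 10, both with and without the block. Lists were tested there only after the data were seen, so these splits alone cannot exclude chance. That count of 14, at the preset correlation, depends on the libraries and the setting. It was 9 without Control replicate 1, 7 with surrogate variables and 7 in the 30 libraries of 1 name series. An estimated correlation left 4 and fry 4, and no splits were drawn for any of these settings.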

How the results depend on the processing

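Alternatives added after the data were seen were all barcodes of at least 500 UMIs, the fits without cerebellar-type clusters, the lower minimum of nuclei, the lists outside classes, the block of deposit order, the cerebellar share as a covariate and the tests that left out 1 library; the others were fixed before the data were examined. No paired analysis was possible because the labels pair no Control with an IVH brain and replicate numbers follow only the order of deposit. With the block of deposit order as a term there were 9 genes over all nuclei, 29 in barcodes of at most 100 UMIs and 5 within classes, with 1 each in cluster 8, excitatory and oligodendrocyte precursor-like nuclei, 1 in microglia and 1 in cluster 18. The lists called were 3 within classes, 7 over all nuclei and 14 in barcodes of at most 100 UMIs, and Ttr was 0.0082 in inhibitory nuclei. At 50 nuclei per library 7 classes were left with the same counts as before, so that setting tested nothing. Apobec1 and Spp1 over all nuclei kept their direction and passed under 10 of 10 alternatives, and Hmox1, Spp1, Msr1, Gpnmb, Lgals3, Lyz2, Fcgr3a, Ctsz and Cd68 in barcodes of at most 100 UMIs under 6 of 6. Cp over all nuclei did not pass with nuclei of at least 1000 UMIs (adjusted p = 0.0876), and Itgal and Ly86 did not pass with a depth covariate or with all barcodes of at least 500 UMIs. Nav3 in microglia did not pass without a low-count filter, in 30 libraries or with doublets kept (adjusted p up to 0.351). Cfb and C1r did not pass under 2 alternatives each and C1s under 1. The cause was not tested for the values that follow. DESeq2 gave 19 genes over all nuclei and 55 in barcodes of at most 100 UMIs, with Cdkn1a at -0.0021 there. Without a low-count filter there were 41 in those barcodes (Cdkn1a -0.00075), 5 within classes (1 in cluster 18, 1 in cluster 33, 1 in ependymal-like, 2 in oligodendrocyte precursor-like and 0 in microglia or macrophage-like nuclei) and, in a class added later, 2 in oligodendrocyte-like nuclei. With surrogate variables there were 28 over all nuclei, 105 in barcodes of at most 100 UMIs and 15 within classes, with 3 in microglia or macrophage-like, 8 in oligodendrocyte precursor-like and 1 each in excitatory, inhibitory and fibroblast-like nuclei and in cluster 18. That setting turned Cdkn1a to 0.018 over all nuclei and -0.062 in the low-UMI barcodes, Vegfa to 0.0089 there, Hba-a1 to -0.036 in endothelial-like nuclei, and Ttr to 0.087 in astrocyte or radial glia-like, -0.17 in cluster 10, 0.033 in cluster 37, 0.17 in cycling progenitor-like and 0.069 in inhibitory nuclei. The 30 libraries of 1 name series, with fewer samples, gave 10 genes over all nuclei, 15 in barcodes of at most 100 UMIs and 0 within classes, microglia (0) and cluster 18 (0) included (edgeR; 157 and 226 at an unadjusted p under 0.05). They turned Cdkn1a to 0.017 over all nuclei and -0.0060 in the low-UMI barcodes, Vegfa to 0.022 there and -0.062 in astrocyte or radial glia-like nuclei, Ttr to -0.019 in cluster 10 and -0.033 in fibroblast-like nuclei, and the share difference of choroid plexus to 0.0169 points. A depth covariate gave 1 gene within classes, 0 in cluster 18, Vegfa 0.0024 in cluster 7, and Ttr -0.069 in excitatory, -0.0077 in fibroblast-like and -0.039 in striatal nuclei. With doublets kept there were 0 within classes, in microglia (0) and in cluster 18 (0), Hba-a1 was -0.082 over all nuclei and -0.038 in endothelial-like nuclei, and Ttr was -0.085 in fibroblast-like nuclei. Nuclei of at least 1000 UMIs gave 2 genes in microglia or macrophage-like nuclei and a share difference of inhibitory nuclei of 0.00493 points, which was 0.323 without cerebellar-type clusters. All barcodes of at least 500 UMIs gave 18 genes within classes, 17 of them in microglia or macrophage-like nuclei (3 higher and 14 lower). There Hba-a1 was -0.015 over all nuclei and -0.036 in endothelial-like nuclei, Hbb -0.012 in endothelial-like nuclei, and Ttr -0.019 in cluster 10, -0.35 in microglia and 0.091 in endothelial-like nuclei. The same setting put share differences at -0.0560 (mural-like) and -0.00755 points (fibroblast-like). Barcodes of at most 50 UMIs gave 13 genes and Vegfa 0.018. As centred log-ratios the share differences of cycling progenitor-like and fibroblast-like nuclei were -0.124 and -0.118. Of the lists, an estimated correlation left 0 within classes, 1 over all nuclei and 4 in barcodes of at most 100 UMIs, and fry 0, 1 and 4. Surrogate variables gave 6 within classes and 7 in barcodes of at most 100 UMIs, and the 30 libraries gave 7 in the latter. Leaving out each library gave 2 to 11 genes over all nuclei, 14 to 24 in barcodes of at most 100 UMIs, 0 to 2 in cluster 18 and 0 to 2 in microglia. It gave 3 to 4 lists within classes, 6 to 9 over all nuclei and 9 (without Control replicate 1) to 18 in barcodes of at most 100 UMIs, and Hba-a1 in striatal nuclei was -0.0096 without IVH replicate 13. Of the results that answer no comparison by themselves, 1227 values were the same in direction and call, 17 stronger and 23 weaker.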

Other observations

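The values here were picked out only after they were seen, and no further tests were run on them. In microglia or macrophage-like nuclei, Sparc, which encodes a secreted matrix-binding protein, had 361 ± 98.7 CPM in Control and 197 ± 79.8 CPM in IVH, a log2 fold change of -0.85 ± 0.18 that did not pass (edgeR adjusted p = 0.0583, 16 of 16 IVH libraries below the Control median). Apobec1 had 0.79 ± 0.19 in those nuclei, also not passing (adjusted p = 0.188, 14 of 16 above).

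Haemoglobin RNA in single libraries set several values of Hbb. In astrocyte or radial glia-like nuclei Hbb had a log2 fold change of 1.95 (adjusted p = 0.661), and 0.19 without IVH replicate 13. In excitatory neuron-like nuclei it had 1.73 (adjusted p = 1.00), and 0.63 without IVH replicate 7. Over all nuclei Hbb had 0.12, and 0.53 without Control replicate 7. In cluster 7 it had -1.01, and -0.32 without Control replicate 8. Cluster 41, with 283 nuclei, was led by Hba-a1 and Hbb.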
